A study of Drosophila melanogaster with 6 samples.

How the data were processed

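Gene expression was measured on 6 Affymetrix Drosophila Genome 2.0 arrays, a 3' oligonucleotide array with 1 biotin channel, each hybridised with labelled RNA from whole heads of Drosophila melanogaster. Per the labels, the flies were females of the w1118 strain, a white-eyed laboratory stock, mated for 48 hours with males of the same background. They were then kept for 7 days on normal medium or on the same medium with 20% (w/v) coconut oil. The diet temperature was 23 degrees C in most cases, and which samples were exceptions is not given in the sources used here. Each RNA sample came from 25 to 50 heads, shaken off snap-frozen flies. Each diet had 3 samples, described in the series' design text as biological replicates.

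The deposited values are signal intensities on a linear scale, 1 column per array, with no replicates pooled. Per the submitters' processing notes they were made with Affymetrix Expression Console; its version and the method that summarises probes into probe sets are not given in the sources used here. The mean over the 18952 probe sets of each array, without the top and bottom 2%, was 500 on every array, the mark of 1 scaling factor per array. Such scaling leaves the shape of each array's distribution untouched, and the array medians ranged from 59.0 to 86.2. RNA that one array carries and another lacks therefore lowers every other gene of that array slightly. The plan had foreseen no further normalization only for medians within 0.1 log2 of each other. The medians differed by more; the planned test on the values as deposited was kept, and quantile normalization and median centring were run as alternatives. No column of the table was left unused.

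From the intensities, log2 values were computed after setting values below 1 to 1, which affected 2010 values. The 183 control probe sets were left out and 18769 probe sets were tested. Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), high fat minus normal diet, on all 6 arrays without covariates, and adjusted by Benjamini-Hochberg, with the threshold at an adjusted p of 0.05. Positive log2 changes are higher on the high fat diet. Of the tested probe sets, 13647 had 1 gene symbol in the platform annotation, 402 had several and 4720 had none here; no gene was named from the last 2 kinds. The gene table of the reference annotation matched 13544 of the single-gene probe sets by Entrez identifier and changed 0 symbols. For the 11982 genes so named, the probe set with the highest mean stood for the gene. Array annotations can be old, and some well-known head genes have no named probe set here and were not analysed here.

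The level of background was set for each array at the 95th percentile of 50 control probe sets named for proteins of other organisms, and lay between 15.2 and 21.8 signal units. This definition was chosen after the data were seen. Between 65.3% and 70.0% of probe sets lay above it on each array. Where a gene lay below background on every array of a diet, only a lower bound of the ratio is given: the mean log2 signal of the brighter diet minus the mean, per array, of the higher of background and the gene's own signal. No ratio is given for genes below background in both diets. The number of arrays, 3 per diet, limits the precision.

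The 34 gene lists, 25 of pathways and 9 of cell type markers, the tests, the thresholds, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names, in each direction, up to 10 genes whose 3 values of one diet lie beyond the 3 of the other, taken by size of change among those past the threshold and filled by the smallest unadjusted p where fewer than 10 pass. For each list it names up to 4 members past the threshold or, with none, the 2 with the smallest unadjusted p, given as values. Genes outside the rule are said to have been chosen after their values were seen. The lists were tested with limma's camera with a preset correlation of 0.01 between genes, Benjamini-Hochberg adjusted over the 34 lists, and again with an estimated correlation and with fry. camera compares a list with all other genes, so its direction can differ from the sign of the list's median. Single members were also adjusted over the list alone.

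The arrays of a diet were compared before averaging. Pearson correlations of log2 signal across probe sets, which are not independent replicates, ranged from 0.939 to 0.955 over the 15 pairs of arrays, and at most 0.00528% of values were identical between any pair. Normal diet replicate 2 correlated more with high fat diet replicates 1, 2 and 3 (0.954, 0.952 and 0.955) than with normal diet replicates 1 and 3 (0.948 each). Over probe sets above background on all arrays, the SD of its log2 differences was 0.31, 0.39 and 0.31, against 0.46 and 0.50. By these measures the arrays did not group by diet. The probe set test was tested on simulated data made from the real means and spreads of all 18769 probe sets, with 200 of them changed. It recovered 14.9% of changes of 1 log2 unit, 38.8% of changes of 2 and 66.7% of changes of 4, with 2 false calls; among the brighter probe sets the shares were 32.3%, 78.6% and 96.9%. With the variance trend and robust moderation 22.4%, 38.8% and 68.2% were recovered, with 0 false calls. Simulated values were not held at the floor of 1 signal unit, so falls of dim probe sets may be recovered more often than in real data. The shares for the brighter probe sets counted calls in either direction. A simulated shift of 0.4 log2 in the neuron list was recovered, and 0 lists were called where nothing was shifted. The simulated genes varied independently of one another, whereas the estimated correlation within the real neuron list was 0.41. The simulation therefore does not show how often camera with the preset correlation calls unshifted lists of correlated genes.

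Alternatives covered quantile normalization, median centring, leaving out the dimmer probe sets, variance trend with robust moderation, array weights, the replicate number as a block, an offset of 16 before taking logs, keeping control probe sets, other thresholds, 1 probe set per gene, the mean of all probe sets of a gene, other set tests and leaving out each array in turn. Chosen after the data were seen were a filter on background with and without trend and robust moderation, the fit without normal diet replicates 1 and 3, the mean signal of 5 germ line genes as a covariate, and Pcyt1 in place of CCT1 in the lipid synthesis list. The germ line covariate is nearly tied to diet and leaves 3 residual degrees of freedom. Changes fitted with it are therefore imprecise and cannot be read as diet changes corrected for germ line RNA. The list fixed beforehand gave the symbol CCT1 for an enzyme of phosphatidylcholine synthesis, but it matches a chaperonin subunit in the annotation; the main test keeps it as matched. Lists of 23 germ line, 21 early zygotic, 9 larval, 8 Malpighian tubule and 2 spermathecal genes, and a division of the ovary list into 7 germ line and 14 eggshell genes (its other member, nanos, is among the 23), were also drawn up after the data were seen. No genome coordinates are given, because no genome build is named in the sources used here.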

Results

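Whole heads of mated female flies were profiled after 7 days on a normal diet or on a high fat diet, with 3 arrays per diet. The question put to the data was how a week of coconut oil in the medium changes gene expression in the head. Signal is given as the mean log2 value ± SD over the 3 arrays of a diet, and a change is high fat minus normal diet with the standard error (SE) of the limma fit. The arrays reached similar sensitivity: 65.3% to 70.0% of probe sets lay above background, and 10703 of 18769 did so on all 6 arrays. The 3'/5' signal ratio of the Act5C actin controls, a measure of RNA integrity, was 20.4 in high fat diet replicate 2 and between 10.5 and 13.2 on the other 5 arrays.

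Among the genes named by rank and above background on all arrays, those with the smallest p were a cytochrome P450, CG14456 and an odorant carrier on the high side and, as the only one, a member of the fatty acid elongase family on the low side. Cyp4e3, a cytochrome P450 of the CYP4 family, measured 9.25 ± 0.04 on the normal diet and 11.14 ± 0.20 on the high fat diet (n = 3 each), a ratio of 3.71 (log2 change 1.89, SE 0.14, limma adjusted p = 0.0957). Obp28a, an odorant-binding protein, went from 7.03 ± 0.07 to 8.44 ± 0.16 (log2 change 1.41, SE 0.13, adjusted p = 0.128), and CG14456 from 11.37 ± 0.06 to 12.76 ± 0.12 (1.40, SE 0.12, adjusted p = 0.0992). CG18609, a member of the fatty acid elongase family, measured 7.88 ± 0.38 on the normal diet and 5.19 ± 0.12 on the high fat diet, 6.44 times as much on the normal diet (log2 change -2.69, SE 0.22, adjusted p = 0.0992). The naming rule took only genes in which the 3 values of one diet lay beyond the 3 of the other, as they did in 17.7% of all probe sets. In these genes the gap was wider than the spread between replicates, yet none passed the threshold after adjustment over all probe sets.

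**Figure D1:**
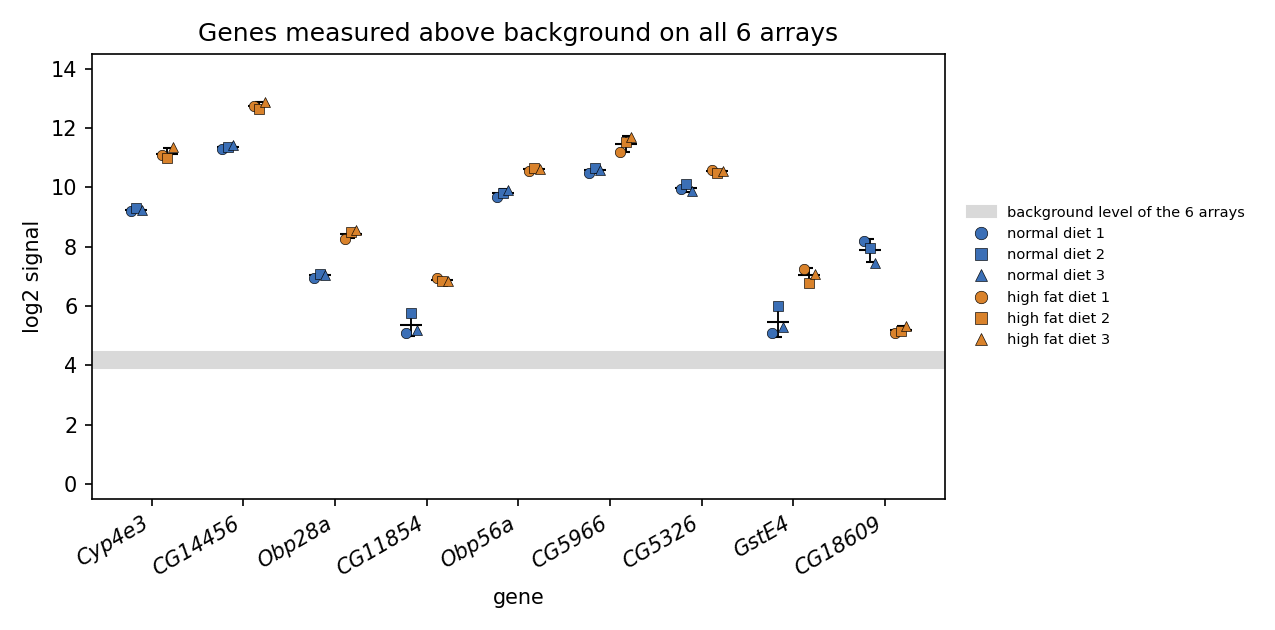
Log2 signal on each array (y axis, log2 units) of 9 named genes that lay above background on all 6 arrays, with the mean and SD of each diet (n = 3) and the range of the arrays' background in grey. Cyp4e3 lies near 9.25 on the normal diet and 11.14 on the high fat diet, and CG18609 near 7.88 and 5.19.

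Across all probe sets, limma called 0 higher and 0 lower on the high fat diet. The smallest adjusted p was 0.0749, and 11 probe sets (4 higher, 7 lower) had an adjusted p under 0.1, of which only 3 were above background on every array of at least 1 diet. At an unadjusted p under 0.05 there were 1475 probe sets, 553 higher and 922 lower, where chance alone gives 938. The diets did not overlap in 17.7% of probe sets, against 10% by chance for 3 against 3. The count depended on how the spread was estimated, on which probe sets were tested and on which arrays were used. Variance trend with robust moderation called 18 higher and 8 lower, with Cyp4e3 (adjusted p = 1.02e-04), CG14456, Obp28a and CG18609 among them. Its lower calls also held osk and yl, genes of the female germ line. Leaving out the dimmer probe sets called 5 higher and 2 lower, with osk among the lower. Leaving out normal diet replicate 2 gave 16 higher and 151 lower. Among the lower were osk, orb and RpS5b and, chosen after their values were seen, bcd and CycB, all active in the female germ line. The bcd call was of a dimmer probe set than the one that stands for this gene elsewhere. The array left out had the least germ line signal of its diet.

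The other genes named by rank on the high side were mostly dim. CG11854 was above background on all 6 arrays (5.35 ± 0.36 and 6.88 ± 0.06; log2 change 1.53, SE 0.21, adjusted p = 0.254). CCKLR-17D3, a receptor for the satiety peptide drosulfakinin, was below background on the normal diet and at 5.72 ± 0.30 on the high fat diet, at least 3.01-fold higher (adjusted p = 0.144). Brd, a small protein acting in Notch signalling, was likewise at least 1.76-fold higher (4.94 ± 0.22, adjusted p = 0.144). CG10357 and Cpr49Aa were above background on 1 high fat array each, and CG13041 and eIF4E7 on none. On the low side VhaM9.7-d, a subunit of the proton pump V-ATPase, was below background on the high fat diet and at 4.63 ± 0.05 on the normal diet, at least 1.33-fold lower on the high fat diet (adjusted p = 0.183). CG7573 and comr were above background on 1 normal diet array each, and CG31784, CG1631, CG32277, SmydA-6 and CG31882 on none.

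Among the genes that the planned rule names, the widest measured differences were in osk and yl, genes of the female germ line, which had more signal in heads from the normal diet. osk, which assembles the germ plasm of the egg, measured 10.70, 8.70 and 11.05 on the 3 normal diet arrays and 3.76, 4.02 and 4.29 on the high fat arrays, only 1 of them above background, so that the size of the difference is uncertain (log2 change -6.13, SE 0.66, limma adjusted p = 0.144). yl, the yolk protein receptor of the oocyte, was below background on the high fat diet and at least 9.54-fold lower there (7.47 ± 1.40 on the normal diet, adjusted p = 0.305). In both genes normal diet replicate 2 had the lowest signal of its diet. Among the alternatives, osk passed by limma with trend and robust moderation (adjusted p = 0.0449), without the dimmer probe sets (0.0156) and without normal diet replicate 2 (0.0188). With trend and robust moderation yl passed too (adjusted p = 0.0171). Of the 22 measured members of the ovary list, 17 had a lower mean on the high fat diet and 6 passed when adjusted over the list alone (0 over all probe sets by limma). These were osk, yl and, outside the naming rule and chosen after their values were seen, nanos, bcd, otu and CycB. nanos and bcd are maternal determinants of the body axis, otu acts in germ cell cysts, and CycB is a mitotic cyclin loaded into the egg. The list's median change was -1.14, or -0.42 with dim values raised to background, and it was lower by camera with the preset correlation (adjusted p = 7.35e-04), though not with an estimated correlation (adjusted p = 0.695).

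**Figure D2:**
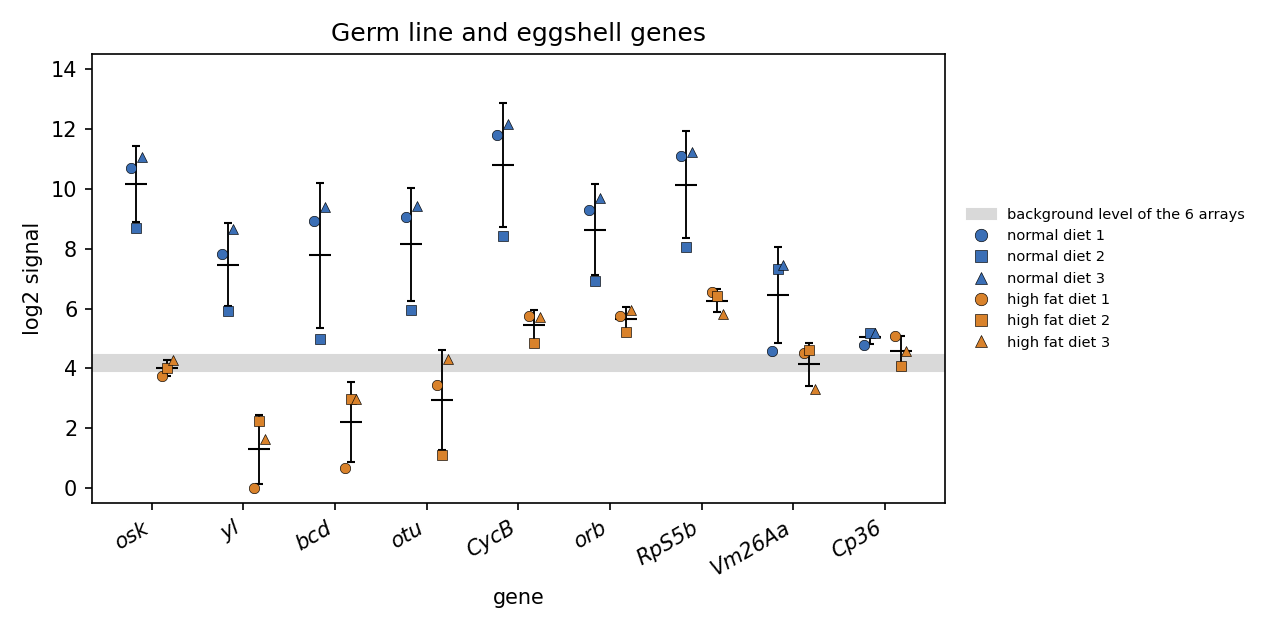
Log2 signal on each array (y axis, log2 units) of 7 genes active in the female germ line (osk to RpS5b) and of the eggshell genes Vm26Aa and Cp36, chosen after their values were seen except osk, yl, orb and RpS5b, with the mean and SD of each diet (n = 3) and the range of background in grey. osk lies at 10.70, 8.70 and 11.05 on the normal diet and at most at 4.29 on the high fat diet.

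Other lists held germ line or ovary genes, of which orb and RpS5b had the same array profile, highest on normal diet replicates 1 and 3. orb, an RNA-binding protein of oocytes that sits in the learning and memory list, measured 9.30, 6.91 and 9.70 on the normal diet and 5.64 ± 0.39 on the high fat diet (log2 change -2.99, SE 0.79, adjusted p = 0.610). RpS5b, a ribosomal protein paralog enriched in the ovary, measured 11.11, 8.07 and 11.21 against 6.27 ± 0.38 (log2 change -3.86, SE 0.93, adjusted p = 0.579), while the ribosomal protein list as a whole had a median change of 0.03 (34 members, camera adjusted p = 0.739). RpS19b, a germ line paralog, was near background on the normal diet (4.36 ± 0.23) and below it on the high fat diet. The small heat shock proteins Hsp26 (log2 change -1.74, SE 0.33) and Hsp27 (-2.69, SE 0.66), both known from nurse cells as well as from stress, passed when adjusted over the list of 11 heat shock and Turandot genes alone (adjusted p = 0.0330 and 0.0481) and not over all probe sets. With the germ line covariate, a fit chosen after the data were seen, Hsp26 was at -0.39 and Hsp27 at 0.53. That covariate is nearly tied to diet, so these are not changes corrected for germ line RNA. The list itself did not pass (median -0.09, adjusted p = 0.607).

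Genes of nervous tissue, eye and muscle rose slightly together by camera with the preset correlation. The pan-neuronal list had 18 of 20 members with a higher mean on the high fat diet (median change 0.22, adjusted p = 2.72e-05), the photoreceptor list 14 of 15 (0.18, adjusted p = 4.12e-04) and the muscle list 18 of 20 (0.26, adjusted p = 1.03e-05). With an estimated correlation each of these lists had an adjusted p = 0.695. Examples are the GABA receptor Rdl (0.33, SE 0.12) and the calcium channel cac (0.41, SE 0.16). Others are the light-activated channel trp (0.33, SE 0.13), the photoreceptor surface protein chp (0.41, SE 0.15) and the muscle proteins Tm2 (0.49, SE 0.16) and bt (0.38, SE 0.14). No member passed on its own. Quantile normalization ended the call of the photoreceptor list (median 0.14, adjusted p = 0.0810), and with germ line signal as a covariate, a fit chosen after the data were seen, the medians were -0.05 for neuron, -0.13 for photoreceptor and -0.0035 for muscle. Because the covariate is nearly tied to diet, medians fitted with it, here and below, are not changes corrected for germ line RNA. Over the 55 genes of these lists the high fat mean exceeded normal diet replicates 1, 2 and 3, with osk at 10.70, 8.70 and 11.05, by medians of 0.20, 0.12 and 0.35. In the muscle and neuron lists replicate 1 (0.20 and 0.15) lay nearer to replicate 2 (0.19 and 0.11) than to replicate 3 (0.40 and 0.35), and in the photoreceptor list about midway (0.21, against 0.10 and 0.33).

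Neuropeptide and monoamine genes also rose as lists (22 of 28 members, median 0.16, camera adjusted p = 0.00191; 15 of 20, median 0.17, adjusted p = 0.00454). With an estimated correlation each had an adjusted p = 0.695, and with the germ line covariate their medians were -0.07 and -0.17. Crz, the stress peptide corazonin, was higher by 0.47 (SE 0.11) and Nplp3 by 0.44 (SE 0.13). The serotonin receptor 5-HT2B, above background on 1 normal diet array and all high fat arrays, was higher by 0.84 (SE 0.12) and passed when adjusted over its list alone (adjusted p = 0.0154), though the mean of all its probe sets gave -0.27. Tdc1, a tyrosine decarboxylase of tyramine synthesis, was higher by 0.64 (SE 0.21). The hemocyte list rose by camera (11 of 13 members, median 0.15, adjusted p = 0.00833), though not with an estimated correlation (adjusted p = 0.695), and its median was -0.19 with the covariate. It held Hml at 0.43 (SE 0.15) and NimC1 at 0.26 (SE 0.12). Learning and memory genes passed as well (22 of 29, median 0.12 with a mean of -0.03, adjusted p = 0.0229), with CanA1, a calcineurin subunit, at 0.37 (SE 0.18). With an estimated correlation the adjusted p was 0.695, after quantile normalization it was 0.0810 with the median at 0.18, and with the covariate the median was -0.13. As drawn up, the learning and memory list shares genes with the neuropeptide and monoamine lists. The median of each of these lists lay under that of the pan-neuronal list (0.22). Whether they rose apart from neuronal genes in general was not tested. Oxidative phosphorylation had the smallest shift of the lists that rose by camera (44 of 63, median 0.05, adjusted p = 0.0343). It held SdhD at 0.31 (SE 0.12) and COX4L, above background on 1 high fat array, at -1.02 (SE 0.53). With an estimated correlation the adjusted p was 0.847, after quantile normalization it was 0.955 with the median at 0.0038, and with the covariate the median was -0.10. Leaving out 1 array ended some calls. Monoamines did not pass without normal diet replicate 3 (adjusted p = 0.0889) or high fat diet replicate 3 (0.153), nor hemocyte without normal diet replicate 3 (0.0889) or high fat diet replicate 1 (0.0783). Learning and memory did not without normal diet replicate 3 (0.173), high fat diet replicate 1 (0.0561) or 3 (0.0675), nor oxidative phosphorylation without normal diet replicate 1 (0.595) or high fat diet replicate 2 (0.458). With the mean of all probe sets of a gene, monoamines (camera adjusted p = 0.0934) and learning and memory (0.205) did not pass. With the replicate block oxidative phosphorylation did not pass (camera adjusted p = 0.0675). Without normal diet replicates 1 and 3, the arrays with osk at 10.70 and 11.05, 2 of the 11 lists passed, muscle and ovary, in a fit chosen after the data were seen. That fit sets 1 normal diet array against 3, so its spread comes from the high fat arrays alone, and the lone array is assumed to vary like them. It does not tell fewer arrays from a dependence on those left out.

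Odorant-binding proteins split, with 28 of 51 higher and 23 lower, while 3 passed when adjusted over the list alone (0 over all probe sets), all higher. They were Obp28a (adjusted p = 0.00487), Obp56a (0.81, SE 0.12, adjusted p = 0.0250) and Obp69a (0.90, SE 0.17, adjusted p = 0.0450), the last chosen after its values were seen. The list passed by camera (median 0.11, adjusted p = 0.0249) but not with an estimated correlation (adjusted p = 0.695) or after quantile normalization (median 0.12, adjusted p = 0.0810). Nor did it pass after median centring (median 0.38, adjusted p = 0.444), without normal diet replicate 1 (0.06, adjusted p = 0.533) or without high fat diet replicate 2 (0.13, adjusted p = 0.0988). The replicate block ended the call of this list too (camera adjusted p = 0.119). The 166 odorant, gustatory and ionotropic receptors, of which 22 were above background on all arrays, did not pass (median -0.04, adjusted p = 0.350), but did with the dimmer probe sets left out (median 0.36, adjusted p = 0.00705). Their 2 members with the smallest p, Ir56c and Gr98c, were below background on every array.

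Every one of the 26 measured proteasome subunits had a lower mean on the high fat diet in the values as deposited, and in 15 the diets did not overlap. The list fell by camera with the preset correlation (median -0.21, adjusted p = 1.03e-05), but not with an estimated correlation (adjusted p = 0.695), and 0 subunits passed on their own by limma. With the germ line covariate its median was 0.18. Centring each array on its median moved the median change of all probe sets from -0.03 to 0.23 and that of the proteasome list to 0.05, with no call (adjusted p = 0.204); relative to all probe sets it stayed lower. The signs of small list medians depend on that shift. Rpn1 was at -0.28 (SE 0.11) and Prosalpha4 at -0.42 (SE 0.18). Against the high fat mean, the median subunit was higher by 0.22 and 0.37 on normal diet replicates 1 and 3 and by 0.09 on replicate 2.

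**Figure D3:**
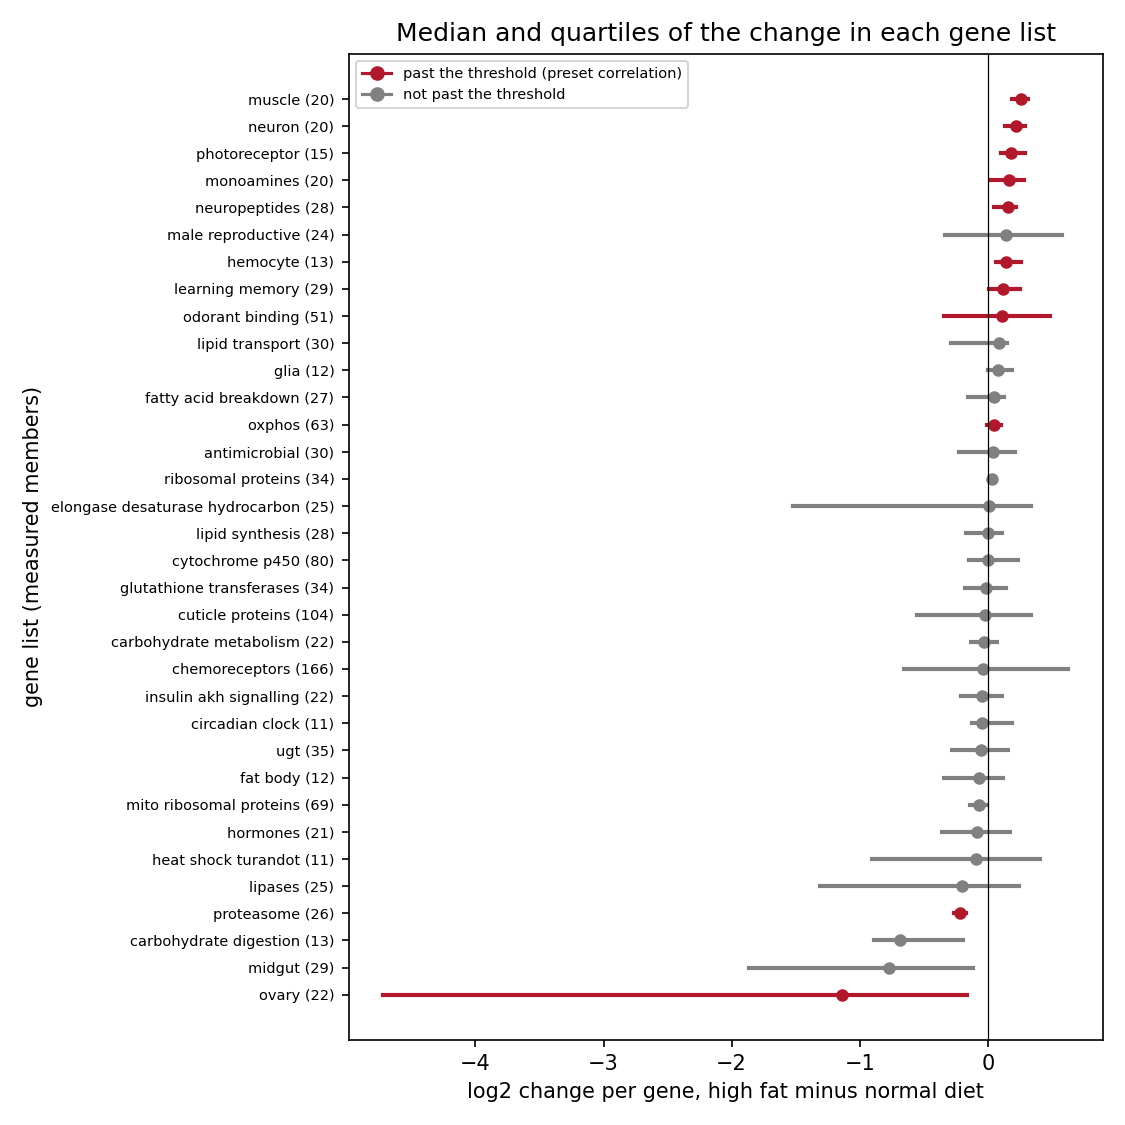
Median log2 change, high fat minus normal diet (x axis, log2 units), of each of the 34 gene lists (y axis, number of measured members in parentheses), with bars from the lower to the upper quartile over members. Red marks the 11 lists past the threshold by camera with the preset correlation, of which muscle (0.26), neuron (0.22) and photoreceptor (0.18) lie highest and ovary (-1.14) lowest.

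Lipid genes differed in single members and did not pass as lists in the main test. In the list of elongases, desaturases and hydrocarbon synthesis, 3 of 25 members passed when adjusted over the list alone (0 over all probe sets). They were CG18609, lower (adjusted p = 0.00130), and the elongase-family genes CG5326 (0.56, SE 0.12) and CG33110 (0.48, SE 0.10, chosen after its values were seen), higher (adjusted p = 0.0399 for each). The list's median change was 0.0059 (camera adjusted p = 0.375), and with the dimmer probe sets left out it was 0.33 and passed (adjusted p = 0.00232). Lipolysis and fatty acid breakdown (27 members) had a median of 0.05 (adjusted p = 0.634), with 0 members past the threshold even over the list alone. CG4586, above background on 1 high fat array, was at -2.67 (SE 0.96; 6.52, 4.60 and 6.63 on the normal diet), and Had1, a hydroxyacyl-CoA dehydrogenase, at -0.47 (SE 0.19). Fatty acid and triglyceride synthesis (28 members) had a median of 7.12e-04 (adjusted p = 0.974), with FASN3, a fatty acid synthase, at -1.57 (SE 0.58; 7.88, 5.71 and 6.94 on the normal diet). Like osk and yl, FASN3 and CG4586 had their lowest normal diet signal on replicate 2, but FASN3 was highest on replicate 1 and osk and yl on replicate 3. With the germ line covariate FASN3 was at 1.11 and CG4586 at -0.51. The synthesis list also held CCT1, at -0.54 (SE 0.21), a chaperonin subunit whose symbol Pcyt1, an enzyme of phosphatidylcholine synthesis, once shared. With Pcyt1 (0.02, SE 0.11) in its place, as seen only after the results, the list had a median of 0.0066 (adjusted p = 0.855), and the second gene named would be FASN2 at -0.47 (SE 0.18). Lipases (25 members, median -0.20, adjusted p = 0.791) included CG5966 at 0.90 (SE 0.17, adjusted p = 0.424), which passed over all probe sets with trend and robust moderation (adjusted p = 0.0313), and CG17097, below background on every array. Lipid transport (30 members, median 0.09, adjusted p = 0.291) held Snmp2 at 0.59 (SE 0.21) and Snmp1 at -0.45 (SE 0.20).

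Detoxification genes did not pass as lists in the main test. The 80 cytochrome P450 genes had a median of -0.0010 (adjusted p = 0.291). They passed as higher without normal diet replicate 2 (median 0.04, adjusted p = 0.0331) and as lower with the germ line covariate (median -0.21, adjusted p = 0.0423). Cyp4e3 passed over the list alone (adjusted p = 0.00248), and its relative Cyp4e1 was at 0.81 (SE 0.18, adjusted p = 0.507). Glutathione transferases (34 members, median -0.01, adjusted p = 0.842) held GstE4 at 1.58 (SE 0.29) and GstT3 at 0.42 (SE 0.11). With the germ line covariate GstE4 was at 0.20 and GstT3 at 0.62. UDP-glycosyltransferases (35 members, median -0.05, adjusted p = 0.974) held Ugt37A3 at -0.45 (SE 0.15) and Ugt303B1, below background on every array. Among 21 hormone genes (median -0.08, adjusted p = 0.791), Hr4, a nuclear receptor of the ecdysone response, was below background on the normal diet and at least 1.62-fold higher on the high fat diet, and passed over the list alone (adjusted p = 0.0202). Hr38 was at 0.46 (SE 0.12). Of 104 cuticle protein genes (median -0.02, adjusted p = 0.291), 1 passed over the list alone, Cpr49Aa (adjusted p = 0.0411), and TwdlW was above background on 2 high fat arrays only. That list passed with the dimmer probe sets left out (median 0.14, adjusted p = 0.00233).

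Lists of nutrient handling, immunity and the clock did not pass in the main test either. Carbohydrate metabolism (22 members) had a median of -0.03 (adjusted p = 0.908), with the sugar-responsive transcription factor sug at 0.44 (SE 0.12) and Pepck2, an enzyme of gluconeogenesis, at 0.65 (SE 0.21). Insulin and adipokinetic hormone genes (22 members) had a median of -0.04 (adjusted p = 0.842), and both named members were below background on the high fat diet. Of these, Ilp7 measured 4.50 ± 0.16 on the normal diet and Ilp8 6.63, 2.65 and 6.99, each above background on 2 arrays. Like osk and yl, Ilp8 had its lowest normal diet signal on replicate 2. Antimicrobial genes (30 members) had a median of 0.04 (adjusted p = 0.241), with Listericin at 0.85 (SE 0.19) and BomT3 at 0.31 (SE 0.13). That list passed with array weights (median 0.16, adjusted p = 0.0125) and without normal diet replicate 2, normal diet replicate 3 or high fat diet replicate 2 (medians of 0.10, 0.15 and 0.18, adjusted p of 0.0461, 0.0372 and 0.0123). Clock genes (11 members) had a median of -0.05 (adjusted p = 0.634), with tim at 0.47 (SE 0.14) and Pdp1 at 0.29 (SE 0.14); the time of day at which heads were taken is not given in the sources used here. Mitochondrial ribosomal proteins (69 members, median -0.07, adjusted p = 0.104) held mRpS18A at -0.36 (SE 0.15) and mRpL39 at -0.31 (SE 0.16), and passed with array weights (median -0.09, adjusted p = 0.0237) and without high fat diet replicate 2 (-0.11, adjusted p = 0.00188). Glia (12 members, median 0.08, adjusted p = 0.0856) held drpr at 0.26 (SE 0.12) and repo at 0.29 (SE 0.14). It passed after median centring (median 0.35, adjusted p = 0.0340), with trend and robust moderation (adjusted p = 0.0483) and without normal diet replicate 2 (median 0.16, adjusted p = 0.0376). Fat body (12 members, median -0.07, adjusted p = 0.974) held Lsp2 at -0.41 (SE 0.18) and fit at -0.29 (SE 0.18), and passed without normal diet replicate 1 (median -0.18, adjusted p = 0.0359). Male reproductive genes (24 members, median 0.15, adjusted p = 0.317), of which 2 were above background on all arrays, held Acp62F at 1.53 (SE 0.57; above background on 1 normal diet array) and Mst57Da, below background on every array.

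Gut genes differed between single arrays more than between diets. The midgut list (29 members) had a median change of -0.77, or -0.20 with dim values raised to background (camera adjusted p = 0.103). It passed after quantile normalization (median -0.69, adjusted p = 0.0379) and after median centring (median -0.50, adjusted p = 5.73e-05). With array weights, without normal diet replicate 3 and without high fat diet replicate 2 it passed as well (medians of -1.04, -1.03 and -0.71). Its median was 0.71 with the germ line covariate, and against the high fat mean the median member was higher by 1.72, 0.07 and 0.36 on normal diet replicates 1, 2 and 3. Jon65Aiii, a digestive protease, measured 9.59, 3.59 and 5.95 on the normal diet arrays and 2.15 ± 0.89 on the high fat diet, and Jon65Aiv 9.31, 3.93 and 5.95 against 2.59 ± 1.58 (adjusted p = 0.610 for each). Carbohydrate digestion (13 members) had a median of -0.69 (adjusted p = 0.165); against the high fat mean, the median member was higher by 2.53, 0.10 and 0.12 on the 3 normal diet arrays. It passed after median centring (median -0.42, adjusted p = 0.0349), and its median was -0.10 without normal diet replicates 1 and 3 and 0.34 with the covariate. It held Mal-B1 at -0.19 (SE 0.12) and Mal-B2 at -0.24 (SE 0.17). In 9 of the 34 lists the median and the direction of the camera test differed in sign, and 0 lists passed with an estimated correlation or by fry's directional test (smallest adjusted p = 0.695 and 0.341). fry's mixed test, for change in either direction, passed 20.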

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

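The background level used in this part was chosen after the data were seen. A single control probe set, left out of the comparison between diets, was above background and higher on all 3 high fat arrays than on any normal diet array, by 0.76 on the log2 scale. It was 1 of 50 such controls without a fly gene that were looked at, and 1 other was above background and higher on all 3 normal diet arrays.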

How the results depend on the processing

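The alternatives with a background filter, without normal diet replicates 1 and 3, with a germ line covariate and with Pcyt1 in place of CCT1 were chosen after the data were seen. Against 0 probe sets higher and 0 lower by limma (1475 at an unadjusted p under 0.05), leaving out the dimmer probe sets called 5 and 2, trend with robust moderation 18 and 8, array weights 1 and 2, the background filter 4 and 2. That filter with trend and robust moderation called 17 and 7, and an adjusted p under 0.1 took in 4 and 7. Leaving out 1 array gave 0 to 16 higher and 0 to 151 lower, with every call made without normal diet replicate 2. The lower calls included germ line genes such as osk, bcd (by a dimmer probe set) and CycB, and replicate 2 had the least germ line signal of its diet. The cause was not tested. Quantile normalization, median centring, the offset of 16, kept controls, 1 probe set per gene and the 1.5-fold threshold called 0 and 0. Of 11 gene lists past the threshold, camera with an estimated correlation kept 0 and fry 0, quantile normalization 7, median centring 9, the mean of all probe sets 9, and leaving out 1 array 8 to 11 (all 11 only without normal diet replicate 2). With other arrays or terms, 2 passed without normal diet replicates 1 and 3 and 1 with the covariate (cytochrome P450, lower), which shared 0 with the 11. The first of these fits has 1 normal diet array, assumed to vary like the high fat arrays, which alone supply its spread. The covariate is nearly tied to diet and leaves 3 residual degrees of freedom. Same-numbered arrays did not deviate together (correlations of -0.02, -0.0034 and 0.01), which gave no sign of pairing by number. These correlations do not exclude shared handling, which the labels do not give. With the replicate block 0 and 0 probe sets and 9 lists passed. Signal over background limits the rest: 8066 probe sets were below background on at least 1 array, and the median SE of a log2 change was 0.26 over all probe sets and 0.16 over those above background on all 6 arrays.

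Of 1501 values of 83 named genes under the alternatives, 1440 kept direction and side of the threshold, 37 newly passed and 24 changed direction. No named gene had passed in the main fit, so keeping its side meant staying uncalled. Kept values could still change in size. With the germ line covariate GstE4 went from 1.58 to 0.20, and Cyp4e3 from 1.89 to 1.94. Of 711 values of gene lists, the counts were 553, 20 and 86, and 52 no longer passed. The lists newly past the threshold were midgut in 5 settings (medians of -0.50 to -1.04), antimicrobial in 4, glia in 3, mitochondrial ribosomal proteins in 2, and carbohydrate digestion, elongases and desaturases, chemoreceptors, cuticle, fat body and cytochrome P450 in 1 each. The list test compares a list with all other genes, and each list below whose direction turned is given with its median log2 change; the cause was not tested. Under quantile normalization they were fatty acid breakdown 0.032, lipases -0.0065, carbohydrate metabolism -0.095, glutathione transferases 0.012, glycosyltransferases 0.0093, ribosomal proteins -0.023 and oxidative phosphorylation 0.0038, and the gene Mal-B1 was at 0.014. Under median centring they were lipid synthesis 0.27, lipases 0.067, elongases and desaturases 0.27, insulin signalling 0.23, chemoreceptors 0.23, mitochondrial ribosomal proteins 0.20, cuticle 0.25 and male reproductive 0.41, with Mal-B1 at 0.074 and Mal-B2 at 0.025. Without the dimmer probe sets they were insulin signalling -0.014, hormones -0.081 and fat body 0.033. With trend and robust moderation hormones turned, at -0.081. With array weights glycosyltransferases 0.037 and fat body -0.011 turned. With the background filter, with or without trend and robust moderation, insulin signalling -0.014, glycosyltransferases -0.0078 and fat body 0.033 did. With Pcyt1 in place of CCT1, the chaperonin gene that the symbol in the list matches, lipid synthesis turned, at 0.0066, and 11 lists passed. By fry they were carbohydrate metabolism -0.032 and ribosomal proteins 0.032. With the mean of all probe sets they were lipid synthesis 0.00071, glycosyltransferases -0.050 and hormones -0.081, with 5-HT2B at -0.27. Without normal diet replicates 1 and 3 they were fatty acid breakdown -0.011, lipases -0.35, lipid transport 0.023, carbohydrate digestion -0.099, carbohydrate metabolism -0.10, antimicrobial -0.099 and cytochrome P450 -0.065. Also turned were glutathione transferases -0.046, hormones -0.035, ribosomal proteins -0.069, oxidative phosphorylation -0.014 and cuticle -0.018. Leaving out 1 array turned lists whose medians then ranged over these values: fatty acid breakdown 0.0058 to 0.098, lipid synthesis -0.051 to 0.039, lipases -0.48 to -0.011, carbohydrate metabolism -0.092 to 0.0024, insulin signalling -0.062 to 0.025. The others were antimicrobial -0.12 to 0.18, glutathione transferases -0.073 to 0.0022, glycosyltransferases -0.088 to 0.083, hormones -0.066 to -0.0074, ribosomal proteins -0.066 to 0.081 and fat body -0.18 to 0.017.

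With the germ line covariate 2 of the 11 lists kept their direction and 20 of the 83 named genes changed sign, 0 of them past the threshold in either fit. The lists that turned were fatty acid breakdown -0.012, lipid transport -0.069, carbohydrate digestion 0.34, carbohydrate metabolism -0.21, antimicrobial -0.21 and cytochrome P450 -0.21. Glutathione transferases -0.16, chemoreceptors -0.12, learning and memory -0.13, clock -0.017, neuropeptides -0.073, monoamines -0.17 and hormones -0.13 turned as well. So did ribosomal proteins -0.18, mitochondrial ribosomal proteins 0.061, oxidative phosphorylation -0.098, proteasome 0.18, cuticle -0.13 and neuron -0.049. The rest were photoreceptor -0.13, glia -0.11, muscle -0.0035, hemocyte -0.19, midgut 0.71 and male reproductive -0.41. The genes were FASN3 1.11, CCT1 0.40, Mal-B1 0.11, Ilp8 2.81, Hsp27 0.53, orb 1.53, CanA1 -0.30, Pdp1 -0.085. They also included RpS5b 0.94, mRpS18A 0.13, mRpL39 0.33, Prosalpha4 0.20, TwdlW -0.39, cac -0.11, trp -0.013, bt -0.029, Hml -0.12, Jon65Aiii 2.52, Jon65Aiv 2.82 and Acp62F -0.52.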

Other observations

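The tests of eggshell genes, of single normal diet arrays, of the size of the changes in bright genes against head markers, and of all lists drawn up beyond the 34 were chosen after the diets' values had been seen. These lists were chosen without looking at their members' values, except the division of the ovary list and the gene nanos. A set of 23 germ line and maternally loaded genes, 1 of which (nanos) is also in the ovary list, had a median change of -2.45 (-2.31 with dim values raised to background, and -2.30 as measured without nanos); in 17 of them all normal diet arrays lay above all high fat arrays, and in 1 the reverse. Their medians stood 2.85 and 3.41 log2 above the high fat mean on normal diet replicates 1 and 3 and 0.56 above it on replicate 2. Chosen after their values were seen, dhd, a thioredoxin of the egg, measured 12.79, 9.84 and 13.22 on the normal diet and at most 5.69 on the high fat diet. BigH1, the embryonic linker histone, was at least 10.9-fold lower on the high fat diet, and nanos, chosen likewise, at least 33.9-fold lower. Of the 23, 15 were above background on all 3 high fat arrays too.

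Genes of other abdominal organs behaved differently from one another. Chosen after their values were seen, Cyp4g1, an enzyme of cuticular hydrocarbon synthesis in oenocytes, measured 12.64, 7.59 and 11.01 on the normal diet arrays and 7.24, 8.22 and 7.51 on the high fat arrays, and the elongase-family gene CG16904 measured 8.78, 4.74 and 7.48 against at most 4.42. The digestive protease alphaTry measured 9.61 and the maltase Mal-A1 10.56 on normal diet replicate 1, against at most 5.60 and 7.19 on the other 5 arrays. The 8 Malpighian tubule genes had a median change of 0.07, and of the 2 spermathecal genes Send1 was below background on every array and Send2 above it on normal diet replicate 1 alone.

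Germ line genes were brighter on the normal diet than on the high fat diet. A candidate explanation is RNA of eggs or ovarian germ cells carried into the normal diet head preparations: the 23 germ line genes, of which 22 were picked without their values, had a median change of -2.45 (-2.30 for the 22). Whole ovary tissue with its follicle cells stays open. With dim values raised to background, the median change of the 14 eggshell genes lay 2.18 above that of these 22 (-0.04 against -2.23; interquartile range of the eggshell genes 0.53). As measured, however, the eggshell median was 0.75 and 0.62 above the high fat mean on normal diet replicates 2 and 3 (-0.49 on replicate 1). With dim values raised to background it was 0.50 and 0.34 above on replicates 2 and 3 (-0.29 on replicate 1). Vm26Aa, chosen after its values were seen, measured 7.32 and 7.44 on these 2 arrays, against at most 4.60 on the others. Only 5 of the 14 were above background on all normal diet arrays. Developed embryos or larvae stay open too. The lower of their 2 list medians was -0.41, for larval genes (0.19 for early zygotic genes), above the bound of -0.5 set beforehand but by less than the larval genes' interquartile range of 0.62. The comparison with that range was not part of the rule set beforehand. Of the 30 members 2 were non-overlapping in the same direction, and only 8 were above background on all normal diet arrays. With dim values raised to background both list medians were 0.09, so the test rests on values near the floor and decides nothing. Whether flies on the high fat diet held fewer eggs, or heads were separated from bodies less cleanly in the normal diet samples, was not tested.

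The muscle, neuron and photoreceptor lists were slightly higher on the high fat diet. Quantile normalization left 0.844 of their median change (0.21 against 0.24), which meets the bound set beforehand as speaking against array scaling. It also moved the median change of all probe sets from -0.035 to 0.035, however, so less of the lists' lead over all probe sets was left. The photoreceptor list then no longer passed (camera adjusted p = 0.0810). The test therefore does not decide on array scaling. Leaving out high fat diet replicate 2, the array with the highest Act5C 3'/5' ratio, left 0.855, which argues against that array as the whole cause. Dilution of head RNA by body RNA in normal diet replicates 1 and 3 stays open. The median difference from replicate 2 was 0.430 of that from these 2 together, which meets the bound set beforehand as the mark of dilution. Against the single arrays, a comparison chosen after the values were seen, it was 0.337 of that from replicate 3 and 0.591 of that from replicate 1, the last beyond that bound. Replicate 1 had less germ line signal than replicate 3 (2.85 against 3.41 log2 above the high fat mean, medians over the 23 germ line genes). Log2 differences stand for ratios of RNA amounts, and this is a comparison of single arrays. It does not decide whether dilution went in step with that signal. A diet effect on these tissues stays open.

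Cyp4e3, CG14456, Obp28a and CG11854 were above background on all 6 arrays and higher on the high fat diet. The smallest of their changes lay 1.09 above the upper quartile of the muscle, neuron and photoreceptor lists. They were picked by rank from these same data, which favours large changes, so this comparison does not decide on dilution by body RNA. With the germ line covariate Cyp4e3, CG14456 and Obp28a were at 1.94, 1.47 and 1.39, and CG11854 was at 0.48. Quantile normalization left 1.12 of the median change of these 4 genes, and leaving out high fat diet replicate 2 left 1.02, so neither scaling nor that array accounts for it. A response of head tissue to the diet may underlie these changes; a difference in other cells carried with the heads, or in batches, which the labels do not give, was not tested.

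The 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 1475 probe sets with an unadjusted p under 0.05, and the highest of the others 989, so that 1 split gave as many. For gene lists past the threshold the real split gave 11 and the highest other also 11 (2 splits with as many); that other split put normal diet replicates 1 and 3 with high fat diet replicate 2. For probe sets past the threshold the real split gave 0 by limma, as all 10 splits did or exceeded, the highest other giving 1. The 3 other splits that kept normal diet replicates 1 and 3 together gave 969 to 989 probe sets with an unadjusted p under 0.05 and the remaining 6 gave 685 to 774, which points to a structure among the arrays beside diet.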
